A study of Mus musculus with 4 samples.

How the data were processed

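Gastrocnemius muscle of 2 WT and 2 Fundc1-mKO mice was frozen and its RNA was made into sequencing libraries with a NEBNext kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC 0.11.3, TopHat2 2.0.14 and Cufflinks 2.2.1 and the genome build mm10, without saying what each did. The column names are those of a Cuffdiff gene table, per the file headers. The annotation used, the settings, the scaling between groups and the read totals are not given in the sources used here, so the depth of each library is unknown.

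The table gives 1 FPKM per gene and group (fragments scaled to transcript length and to the number of fragments), made by the authors from the libraries of that group, per the file headers. It gives bounds of the authors' interval around each FPKM, the log2 ratio of mKO over WT computed by the authors, a test score in the authors' column for the test statistic, and the authors' p-value and q-value. The authors' p-value goes no lower than 5e-05, and 209 rows stand at that value, so the smallest q-value in the authors' deposited table is 0.00338. Values of single libraries were not analysed here. The intended test, a linear model on values per library, could therefore not be fitted; the design had foreseen this case, and the q-value of the authors' deposited table was counted in its place.

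The table held 25833 rows and 1 empty row. A single gene was named in 23480 rows, several genes in 436 and no gene in 1892, and in 25 rows a spreadsheet had turned the name into a date. Of the single-gene rows 22524 (95.9%) matched a symbol in a table of mouse gene names. The authors tested 14134 rows, left 11676 untested and marked 23 as having too many fragments (HIDATA). Those 23 rows are listed at 0 in at least 1 group and include abundant muscle genes such as Ckm, Acta1 and Ttn. They were left out, except from the FPKM totals behind the equal-totals scaling. A symbol present in several tested rows was represented by the row with the highest mean. This left 12490 tested symbols, 10487 of them with a mean FPKM of at least 1.

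Starts of loci were 1 below the RefSeq start in 7589 genes with the same end and equal to it in 214, so 1 was added to each start and coordinates are given counting from 1, in mm10. Unnamed loci were placed on genes by overlap with GENCODE release M21, which uses the same assembly.

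The authors' interval is symmetric about the FPKM where it does not reach 0. When the distance from the FPKM to a bound was taken as 2 SD and carried to the log2 scale, the log2 ratio over its SE came within 1% of the authors' test statistic in 99.9% of the 14100 rows with a finite statistic, so this SE is printed for the log2 ratio of Fundc1. It is the error the authors' software assigned, not a spread between animals that can be checked here. The authors' p-value is smaller than a normal reading of that statistic: 1930 tested rows had a p under 0.05 in the authors' deposited table and 238 by the normal reading, while a normal reading of the doubled statistic passed 537 rows after Benjamini-Hochberg adjustment.

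Genes were named by a rule fixed before the data were examined: Fundc1 first, then the 12 largest rises and 12 largest falls on log2(FPKM + 1) among single-gene rows with a q under 0.05 in the authors' deposited table and a mean FPKM of at least 1, then up to 4 members of each gene list. The 35 gene lists were fixed at the same time: metabolic, mitochondrial, stress and fibre genes, markers of other cell types of muscle, neighbours of Fundc1 and sex-linked genes. For each list with at least 5 measured members, the median log2 ratio of FPKM + 1 was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. A list's percentile describes these groups and is not a test across animals. A fold between groups is the plain ratio of FPKM, and log2 ratios of lists carry a pseudocount of 1, which understates changes of weakly expressed genes. "Adjusted over the list alone" means Benjamini-Hochberg adjustment of the authors' p within the list.

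The list procedure was tested on simulated data. Of 50 simulated lists of 15 genes without a shift 4 fell outside the central 95% of random lists. All 50 lists shifted by 0.3 on the log2 scale fell below it. The simulated members were drawn independently, so this does not show how often a list of genes that vary together falls outside without a genotype effect. The normal reading of the statistic was tested on 10474 simulated genes with 200 changed 2-fold, and it recovered 77.0% of them with 3.75% false calls. The simulated errors were normal with the same SE that the test used. This therefore cannot show whether that SE or the normal reading is right for the real table. Changes smaller than 2-fold were not simulated. Alternatives tried were other pseudocounts, minimum FPKM values, thresholds, scalings, row types and random lists without matching. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.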

Results

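Gastrocnemius, the large calf muscle, was profiled by RNA sequencing in 8-week-old C57BL/6J mice. The labels give 2 groups of 2 libraries each, called biological replicates: wild-type controls (WT) and mice in which Fundc1 was deleted in muscle (Fundc1-mKO, mKO below). FUNDC1 is a protein of the outer mitochondrial membrane known as a receptor for mitophagy, the removal of mitochondria by autophagy. The deposited table holds 1 FPKM value per group and gene with the authors' interval, not a value per animal, so the spread between animals and the sequencing depth are not known here. Of 25833 rows, the authors tested 14134, and 23480 rows named a single gene. The comparison implied by the design is mKO against WT, and it asks which transcripts differ in muscle without Fundc1. A gene is said below to rise or fall only when its q in the authors' deposited table was under 0.05.

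Fundc1 was the targeted gene and was lower in mKO by 2.25 on the log2 scale. Its FPKM was 20.1 in WT, with an interval of 16.3 to 23.8, and 4.23 in mKO, with an interval of 3.15 to 5.31. The log2 ratio of -2.25 had an SE of 0.23, derived from those intervals, and q = 0.00338 in the authors' deposited table. The locus (XLOC_025223) spans chromosome X from 17555602 to 17572334 in mm10, where the annotation places Fundc1, a protein-coding gene on the minus strand. The removed exon is not given in the sources used here, and the FPKM covers the whole gene. Among 6 measured neighbours of Fundc1 on the X chromosome none passed q, 2 had an unadjusted p under 0.05 in the authors' deposited table, and 1 was higher when adjusted over the list alone. Ddx3x, a neighbour that encodes an RNA helicase, was at 84.5 FPKM in WT and 91.8 in mKO.

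Genes of macrophages, extracellular matrix and the immediate early response were lower in mKO muscle, and genes of lipid synthesis and granulocytes were higher. By the q of the authors' deposited table, 448 rows passed, 130 higher and 318 lower in mKO, and the 387 of them that named a single gene split into 88 higher and 299 lower. Most changes were small: the median change of the single-gene rows above 0 in both groups was 1.42-fold, and 46 single-gene rows differed by at least 2-fold. Among single genes with a mean FPKM of at least 1, 74 rose and 233 fell.

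The 12 largest rises, ranked on log2(FPKM + 1), included lipid, granulocyte and adipokine genes. Fasn, the fatty acid synthase, rose 2.16-fold from 1.86 to 4.01 FPKM. Scd1, a stearoyl-CoA desaturase, rose 1.72-fold from 20.9 to 36.0 FPKM. Gid4, a substrate receptor of a ubiquitin ligase complex, rose from 27.0 to 45.6 FPKM, and Erdr1 rose from 45.9 to 74.9. Retnlg and Camp, both genes of neutrophil granulocytes, rose 1.85-fold and 2.25-fold, to 12.3 and 2.31 FPKM. Retn, the adipokine resistin, rose 1.50-fold, and G0s2, an inhibitor of adipose triglyceride lipase, rose 1.45-fold. Ramp1, a receptor activity-modifying protein, rose 1.76-fold, and Cyp2e1, a cytochrome P450, 1.55-fold. The guanylate-binding protein gene Gbp10 rose from 0.819 to 1.96 FPKM and the predicted gene Gm2083 from 2.39 to 4.81. The authors' intervals of both groups lay apart for 8 of these 12 genes.

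The 12 largest falls were led by Stfa3 and Defb6, at 4.04 and 3.83 FPKM in WT and listed at 0 in mKO. Saa3, a serum amyloid A gene of the acute phase response, fell 2.66-fold from 12.9 to 4.84 FPKM. Spp1, which encodes osteopontin, fell 2.48-fold from 21.9 to 8.80 FPKM. Ddit4, a stress-induced inhibitor of mTORC1 signalling, fell 2.11-fold from 44.4 to 21.0 FPKM. Actc1, the cardiac alpha-actin also made by developing skeletal muscle, fell 1.78-fold from 77.6 to 43.6 FPKM. Chil3 and Lgals3, both expressed by macrophages, fell 1.95-fold and 1.72-fold, to 5.18 and 22.0 FPKM. Postn, the matrix protein periostin, fell 1.94-fold to 3.70 FPKM, and Arrdc3, an arrestin-domain gene, fell 1.76-fold to 11.0 FPKM. Krt10 and Dmkn, genes of differentiated epidermis, fell from 2.86 to 1.26 FPKM and from 1.81 to 0.387 FPKM. Intervals lay apart for 11 of these 12 genes. For Stfa3 and Defb6 the mKO interval is 0 to 0, so any WT interval above 0 counts as apart.

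**Figure D1:**
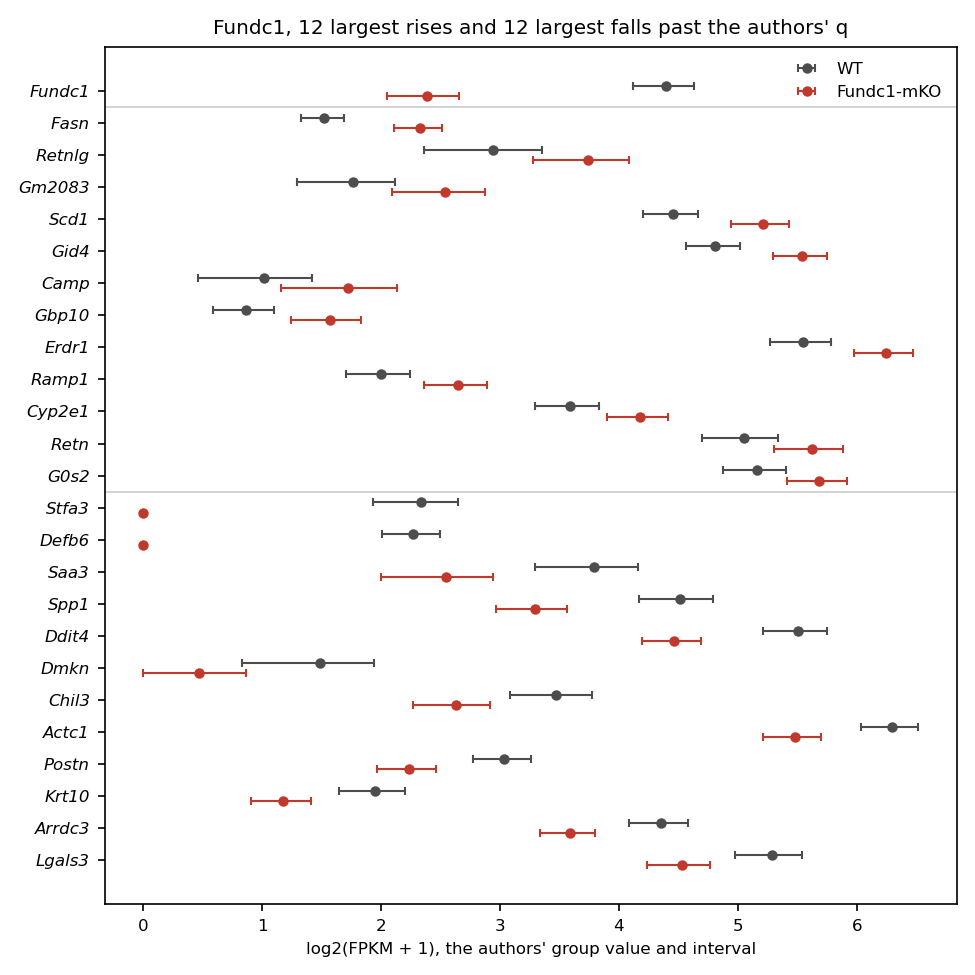
Group FPKM of Fundc1 and of the 12 largest rises and 12 largest falls, as log2(FPKM + 1) on the x axis, with WT in grey and mKO in red; bars are the authors' intervals. Fundc1 drops from 20.1 to 4.23 FPKM, and Stfa3 and Defb6 sit at 0 in mKO.

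The number of calls rests on how the authors' p was obtained. Rows with a p between 0.04 and 0.06 in the authors' deposited table had a median absolute test statistic of 0.981, where a normal distribution puts 1.96; when the statistic was instead read against a normal distribution, 28 rows passed, 15 higher and 13 lower, 23 of them among the 448, a reading chosen after seeing the data. Of the 18 gene lists below with a rise or fall, 13 had no gene past that reading, among them the macrophage, fatty acid, immediate early, atrophy and granulocyte lists. In the others 2 lipid synthesis genes passed it and 1 gene each of the matrix, regeneration, integrated stress response and antioxidant lists. Intervals lay apart for 77 of the 448 rows and for 101 of all 14134 tested rows. A group listed at 0 with an interval of 0 to 0 meets this criterion by itself when the other interval is above 0.

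Macrophage and matrix genes were lower in mKO. All 12 measured macrophage markers were at lower FPKM in mKO and 7 fell, or 11 when adjusted over the list alone. Cd68, a lysosomal glycoprotein of macrophages, fell 1.69-fold from 25.0 to 14.8 FPKM, and the mannose receptor gene Mrc1 fell 1.55-fold from 7.94 to 5.12 FPKM. Ctss and Adgre1 fell 1.38-fold and 1.39-fold. The list's median log2 ratio was -0.31, below all 10000 random lists matched on mean expression. Of 19 measured fibroblast and matrix genes 11 fell and none rose, or 15 fell when adjusted over the list alone, with a median of -0.31, also below all random lists. Epidermal markers were lower as well, with a median of -0.77 over 14 tested genes at any level. Over the 8 with a mean FPKM of at least 1, the minimum of the other lists, the median was -0.89. These markers were listed after seeing the data and with the called genes in view, so a low median was partly built in. The fibrillar collagen genes Col3a1 and Col1a1 fell 1.57-fold and 1.54-fold, to 23.0 and 15.7 FPKM, and the fibrillin gene Fbn1 fell 1.42-fold. Of 7 tendon genes, Thbs4 and Fmod fell, 1.30-fold and 1.23-fold, and the count was 2 when adjusted over the list alone; the median was -0.21 (percentile 0.050).

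Markers of endothelium, fat and granulocytes were not lower in mKO. None of 15 endothelial and mural markers passed q, 3 had an unadjusted p under 0.05 in the authors' deposited table, and their median log2 ratio was 0.05 (percentile 98.8); Emcn was at 7.95 FPKM in WT and 9.25 in mKO. Of 11 adipocyte markers Retn rose, and also when adjusted over the list alone; the list's median was 0.09 (percentile 99.8) and Fabp4 was at 733 and 828 FPKM. All 4 granulocyte and lymphocyte markers measured rose, likewise when adjusted over the list alone, and all were granulocyte genes: Retnlg, S100a8 (136 to 184 FPKM), S100a9 (49.6 to 66.6 FPKM) and Ltf (1.04 to 1.56 FPKM). None of 7 nerve and Schwann cell markers passed q or an unadjusted p under 0.05 in the authors' deposited table, with a median of -0.08 (percentile 8.56). None of 3 red blood cell markers passed, 2 did so when adjusted over the list alone, and Hbb-b2 was at 75.4 and 87.2 FPKM. Xist was at 18.2 FPKM in both groups, and it was the only sex-linked gene that the authors tested. The Y-chromosome genes were listed near 0: Eif2s3y at 0.0269 FPKM in WT and 0.0739 in mKO, Ddx3y at 0.0151 and 0, Uty at 0.00455 and 0.00368, and Kdm5d at 0 in both. Neither group value thus shows a clear male signal.

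**Figure D2:**
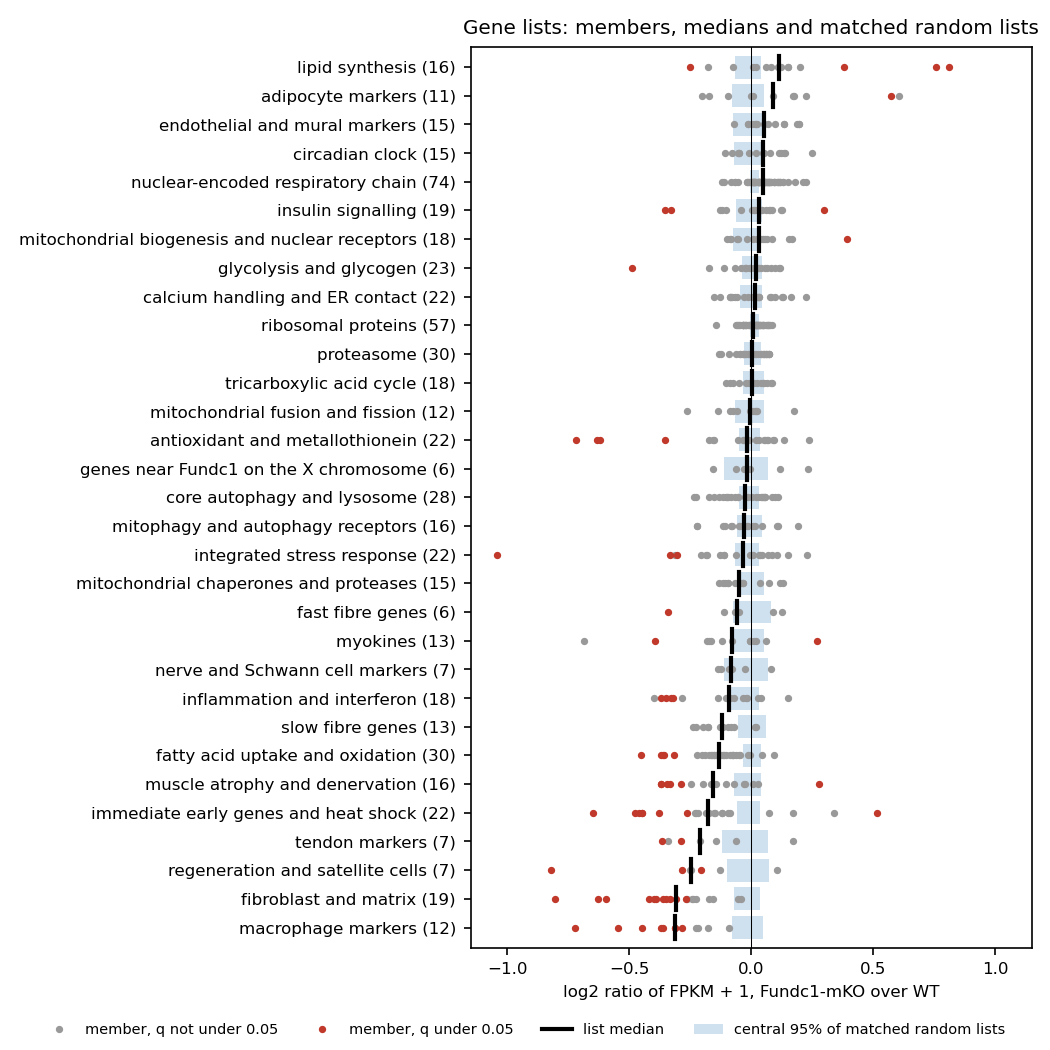
Log2 ratio of FPKM + 1, mKO over WT, on the x axis for the members (points, red when past the authors' q) of the 31 gene lists with a median; black marks are medians, blue bars hold the central 95% of 10000 matched random lists, and counts of measured genes stand in parentheses. Macrophage markers and fibroblast and matrix genes have the lowest medians, both -0.31, and lipid synthesis the highest, 0.12.

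Genes of fatty acid uptake and oxidation were lower and genes of lipid synthesis higher in mKO. Of 30 genes for fatty acid uptake and oxidation 5 fell and none rose, or 6 fell when adjusted over the list alone, and 28 were at lower FPKM in mKO; the median log2 ratio was -0.13, below all random lists. Acot2, a mitochondrial acyl-CoA thioesterase, fell 1.39-fold from 28.7 to 20.7 FPKM. Fabp3, the muscle fatty acid-binding protein, fell 1.29-fold from 2601 to 2014 FPKM. Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell 1.28-fold from 610 to 476 FPKM, and Angptl4, an inhibitor of lipoprotein lipase, fell 1.31-fold. Of 16 lipid synthesis genes Fasn, Scd1 and Thrsp rose and Gpam fell, or 4 rose and 1 fell when adjusted over the list alone; the median was 0.12, above all random lists, or 0.06 (percentile 97.7) at a mean FPKM of at least 5, beside 0.09 for the adipocyte markers. Thrsp, a regulator of lipogenesis, rose 1.33-fold to 15.2 FPKM, and Gpam, an acyltransferase of glycerolipid synthesis, fell 1.19-fold to 66.1 FPKM. Of 23 glycolysis and glycogen genes 1 fell, also when adjusted over the list alone: Pfkfb3, which makes the glycolytic activator fructose 2,6-bisphosphate, fell 1.42-fold from 40.6 to 28.7 FPKM (list median 0.02, percentile 71.9). In insulin signalling, Irs2 and Tbc1d1 fell 1.34-fold and 1.27-fold and Tbc1d4 rose 1.25-fold among 19 genes, with the same counts of 2 and 1 when adjusted over the list alone (median 0.03, percentile 94.6).

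Few genes of mitochondria, mitophagy and autophagy passed. None of 74 nuclear-encoded respiratory chain genes passed q and 3 had an unadjusted p under 0.05 in the authors' deposited table, yet 61 were at higher FPKM in mKO, and the median log2 ratio of 0.05 stood at percentile 99.9; Cox6c was at 1815 and 2119 FPKM. Scaling moved these values: 67 genes were higher with a median of 0.06 at equal medians of the groups, and 68 with a median of 0.08 at equal totals. The totals were 846510 FPKM in WT and 828618 in mKO. They include rows marked HIDATA, such as Tnni2 at 11649 in WT and 0 in mKO. They also include an unnamed locus of 62 bp at 233810 and 218787. The equal-totals values thus depend on a few rows and are a weak alternative. None of 16 mitophagy and autophagy receptor genes passed, with 3 at an unadjusted p under 0.05 in the authors' deposited table and a median of -0.03 (percentile 16.1). Sqstm1, the autophagy receptor p62, was at 325 FPKM in WT and 278 in mKO, and the mitophagy kinase gene Pink1 at 403 and 460. Park2, the parkin gene, was at 3.87 FPKM in WT and 3.17 in mKO. None of 28 core autophagy and lysosome genes passed, with 3 at an unadjusted p under 0.05 in the authors' deposited table and a median of -0.02 (percentile 20.8). None of 18 tricarboxylic acid cycle genes and none of 15 mitochondrial chaperone and protease genes passed either q or an unadjusted p under 0.05 in the authors' deposited table, with medians of 0.00 (percentile 38.1) and -0.05 (percentile 4.99). Of 12 fusion and fission genes none passed over all rows and 1 was lower when adjusted over the list alone, with 2 at an unadjusted p under 0.05 in the authors' deposited table and a median of -0.01 (percentile 51.4). Of 18 genes of mitochondrial biogenesis and nuclear receptors 1 rose, also when adjusted over the list alone: Ppargc1a, the coactivator PGC-1alpha, rose 1.35-fold from 8.16 to 11.0 FPKM (list median 0.03, percentile 96.4). None of the 13 mitochondrially encoded genes was measured.

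Immediate early genes and metallothioneins were lower in mKO, while the medians of the integrated stress response and antioxidant lists lay within the range of random lists. Of 22 genes of the integrated stress response Ddit4, Chac1 and Eif4ebp1 fell and none rose, or 4 fell when adjusted over the list alone, with a median of -0.03 (percentile 23.9); Chac1 fell 1.27-fold from 46.5 to 36.7 FPKM. Of 22 immediate early and heat shock genes 7 fell and 1 rose, or 11 and 2 when adjusted over the list alone, with a median of -0.18, below all random lists. The early transcription factor genes Egr1 and Fos fell 1.67-fold and 1.47-fold, to 5.46 and 5.05 FPKM, Myc fell 1.49-fold, and Nr4a3, an orphan nuclear receptor gene, rose 1.52-fold to 6.93 FPKM. Of 22 antioxidant and metallothionein genes 4 fell and none rose, or 4 fell and 1 rose when adjusted over the list alone (median -0.02, percentile 27.6). The metallothionein genes Mt1 and Mt2 fell 1.65-fold and 1.55-fold, from 949 to 576 FPKM and from 1047 to 675 FPKM, and the haem oxygenase gene Hmox1 fell 1.62-fold. Of 18 inflammation and interferon genes 4 fell, or 6 when adjusted over the list alone: Usp18, Ifit3, Oas1a and Oasl2, interferon-induced genes that fell 1.42-fold to 1.54-fold, beside a median of -0.31 for the macrophage markers. That list's median of -0.09 (percentile 1.26) lay within the range of random lists (percentile 18.3) at a mean FPKM of at least 5.

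Most measured genes of the atrophy and denervation list and of the regeneration and satellite cell list were at lower FPKM in mKO, 13 of 16 and 6 of 7. Of 16 atrophy and denervation genes 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone, with a median of -0.16, below all random lists. Runx1, a transcription factor gene induced by denervation, fell 1.45-fold, the acetylcholine receptor subunit gene Chrna1 fell 1.32-fold, and Trim63, which encodes the ubiquitin ligase MuRF1, fell 1.27-fold from 298 to 234 FPKM. Foxo1 rose 1.23-fold from 11.7 to 14.4 FPKM. Of 7 regeneration and satellite cell genes 3 fell, or 5 when adjusted over the list alone, with a median of -0.25, below all random lists: Actc1, and Myh3 and Myh8, the embryonic and perinatal myosin genes, which fell 1.27-fold and 1.30-fold. Of 13 slow fibre genes none passed and 4 had an unadjusted p under 0.05 in the authors' deposited table; 11 were at lower FPKM in mKO and the median was -0.12 (percentile 0.035), with Mb, the myoglobin gene, at 1770 and 1499 FPKM. Of 14 fast fibre genes 8 carried the authors' mark for too many fragments (HIDATA) and had no usable value; among the other 6, the type IIa myosin gene Myh2 fell 1.27-fold from 487 to 384 FPKM, also when adjusted over the list alone (median -0.06, percentile 4.58).

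Other lists showed few calls. Of 13 myokine genes Fstl1 fell 1.34-fold and Vegfa rose 1.21-fold, also when adjusted over the list alone; the median of -0.08 (percentile 1.53) moved to -0.01 (percentile 47.3) at a mean FPKM of at least 5. None of 15 circadian clock genes passed and 1 had an unadjusted p under 0.05 in the authors' deposited table; the median of 0.05 (percentile 98.2) turned to -0.01 (percentile 51.3) at a mean FPKM of at least 5. None of 22 calcium handling genes passed, with 2 at an unadjusted p under 0.05 in the authors' deposited table and a median of 0.01 (percentile 74.6). None of 57 ribosomal protein genes and none of 30 proteasome genes passed q or an unadjusted p under 0.05 in the authors' deposited table, with medians of 0.01 (percentile 30.8) and 0.00 (percentile 43.7). In all, 10 of the 31 lists with a median lay below and 5 above the central 95% of their matched random lists.

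Rows without a gene name had 55 calls, 40 higher and 15 lower in mKO. Of 20 such loci on annotated immunoglobulin genes 12 rose, among them the kappa constant gene Igkc, from 2.76 to 19.0 FPKM. Some of these loci lie on the same gene. Another 12 calls, all higher in mKO, lay among 16 neighbouring loci between 66080860 and 66389759 on chromosome 6 (mm10). Of the 55 unnamed calls 18 were listed at 0 in WT, where a pass may follow from the 0 itself.

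**Figure D3:**
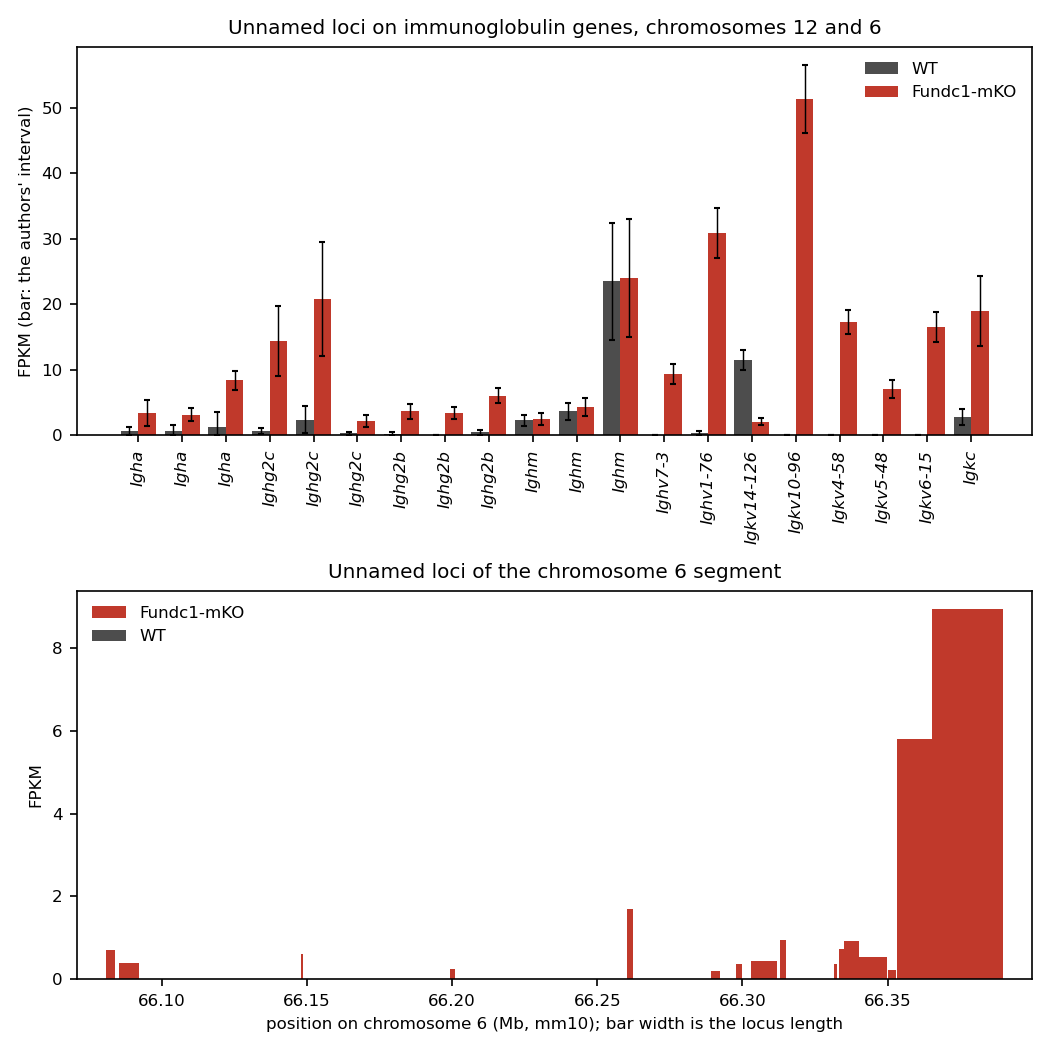
Upper panel: FPKM of 20 unnamed loci on annotated immunoglobulin genes in WT (grey) and mKO (red), with the authors' intervals; lower panel: FPKM on the y axis against position on chromosome 6 in Mb for 16 neighbouring unnamed loci, each bar as wide as its locus. The Igkv10-96 locus stands at 51.3 FPKM in mKO and is listed at 0 in WT, and no locus of the chromosome 6 segment exceeds 0.0131 FPKM in WT.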

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

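The tests on the immunoglobulin loci and on the lower macrophage and matrix genes, and the first test on the chromosome 6 segment, were chosen after the result was seen; the search for similar runs elsewhere was set down before its count was known. The loci in question had no gene name in the table and stand outside the gene comparisons above.

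Immunoglobulin loci were higher in mKO muscle. Of 20 unnamed loci on annotated immunoglobulin genes 12 passed the authors' q as higher in mKO, none as lower and 8 did not pass. Igha, Ighg2c, Ighg2b and Ighm each hold several of these loci, so the counts are of loci and not of separate genes. The kappa constant gene Igkc (chromosome 6, 70726321 to 70726966) went from 2.76 FPKM (1.56 to 3.96) to 19.0 (13.6 to 24.3), and a locus of Ighg2c (chromosome 12, 113287822 to 113288158) from 2.37 to 20.8. Igkv10-96, Igkv4-58, Igkv6-15, Igkv5-48 and Ighv7-3 were listed at 0 in WT and at 51.3, 17.3, 16.5, 7.10 and 9.32 FPKM in mKO. In contrast an Ighm locus (chromosome 12, 113421369 to 113421692) was at 23.5 and 24.0 FPKM, and another kappa variable locus (chromosome 6, 67896343 to 67896615) was at 11.5 FPKM in WT and 2.07 in mKO without passing.

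A general loss of unnamed loci from WT is argued against, since 0.167% of the other 1196 tested unnamed loci were listed at 0 in WT and called higher in mKO. More cells of the B lineage may account for the pattern, but this cannot be told apart from other sources: the 4 tested genes of B lineage and plasma cells, taken at any level, had a median log2 ratio of 0.0762 at a median expression of 0.880 FPKM, too low to decide. Of these, the 2 with a mean FPKM of at least 1, Sdc1 and Xbp1, are also made by other cells. None of the 4 genes passed the authors' q, and 1 was higher when adjusted over the list alone. Jchain was at 0.266 FPKM in WT and 0.504 in mKO, 1.89-fold higher, with q = 0.0669 in the authors' deposited table. Whether 1 or both mKO animals carry the signal stays open, since the table has no values per animal.

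A segment of chromosome 6 had expression almost only in mKO. From 66080860 to 66389759 the table lists 16 consecutive unnamed loci, 13 of them at 0 in WT and none above 0.0131 FPKM there, while in mKO they ranged from 0.198 to 8.94 FPKM and 12 of them passed the authors' q as higher. No GENCODE gene overlaps these loci. Mad2l1, a mitotic checkpoint gene beyond the end of the segment, fell from 1.24 FPKM in WT to 0.690 in mKO. In a list drawn up after seeing the data, 35 of 36 tested proliferation genes were also at lower FPKM in mKO. The fall of Mad2l1 therefore need not be local to the segment.

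A general rise of reads between genes is argued against by the other unnamed loci, whose median log2 ratio was -0.00228 over 1186 loci with a mean FPKM of at least 0.2. An insertion or rearrangement carried by mKO animals is a candidate explanation. The search found 0 other windows of that length with 5 or more unnamed loci at least 10-fold higher in mKO. This count cannot decide, since any cause local to the segment would give it as well. An insertion or rearrangement also cannot be told apart from a difference present in a single animal, because the groups are given as 1 value each.

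The lower macrophage and matrix genes were weighed against 3 technical explanations. A lower share of all cells other than muscle fibres in mKO is argued against by the endothelial and mural markers, whose median log2 ratio was 0.0540 (bootstrap interval over genes 0.00 to 0.13) beside -0.31 (-0.41 to -0.22) for macrophage markers. A scaling difference is argued against by the median of -0.0152 over all 10487 single genes. Skin tissue in the WT samples cannot be told apart from a difference in these cells, because the collagen and macrophage transcripts that skin would bring are not known here. The 14 epidermal markers at any level had a median of -0.770 in the same direction. They were listed after seeing the data and with the called genes in view, so that median cannot decide. A difference in macrophages and fibroblasts, in number or in activity, stays open, as do differences between single animals, and neither was tested.

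A row that joins Rhbdl1, Rhot2, Stub1 and Wdr90 was listed at 113 FPKM in WT and 11405 FPKM in mKO and passed the authors' q. Its mKO interval of 11382 to 11428 FPKM is very narrow for its level, beside 16.3 to 23.8 around 20.1 FPKM for Fundc1 in WT. Whether any of the 4 genes changed was not tested, so the pass is not read as a change of one of them.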

How the results depend on the processing

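The readings of the statistic, the minimum for the lists drawn up later, the interval criterion, the single-gene rows, the unmatched random lists and the Fundc1 ratio without a pseudocount were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the table holds 1 value per group, and for the same reason leaving out each replicate, the replicate block, the linear model with or without a trend, the correlation-adjusted and rotation tests of gene lists and a count-based test were not run. The 448 calls became 335 at a mean FPKM of at least 1, 196 at a mean of at least 5 and 249 at q under 0.01. They became 85 with an absolute log2 ratio of at least 1, 387 among single-gene rows and 77 where intervals lay apart. When the statistic was read against a normal distribution, 28 rows passed. Restricting to tested rows left 448, which was fixed in advance because only tested rows could be called. Calls lower in mKO made up 71.0% of all, 51.8% of those with a log2 ratio of at least 1, 50.6% of those with intervals apart and 46.4% by the normal reading, where 23 of the 28 were among the 448. Among single-gene rows these shares were 77.3%, 73.9%, 76.1% and 68.8%. The more even splits thus come with the unnamed loci, of which 28 of 36, 26 of 28 and 9 of 10 were higher. Of the unnamed calls 18 were listed at 0 in WT, and a WT interval of 0 to 0 lies apart from any interval above 0. Scaling to equal medians or equal totals raised the log2 ratios by 0.02 and 0.03, too little to turn the direction of a call (130 and 318), and a pseudocount does not enter the authors' test. The log2 ratio of Fundc1 was -2.01 with a pseudocount of 1, -2.22 with 0.1 and -2.25 with none, and -1.99 and -2.02 under the scalings. Of 15 lists outside the range of random lists 12 stayed outside it on the same side under every alternative that could be run. The scalings among these alternatives shift all genes nearly alike, so they could hardly move a percentile. Tendon markers, 1 of the 12, had fewer than 5 members at a mean FPKM of at least 5, as had the nerve and Schwann cell markers and the neighbours of Fundc1. At a mean FPKM of at least 5 the median moved to -0.00605 for myokines and -0.0555 for inflammation and interferon, both then inside the range, and turned to -0.0104 for the circadian clock; the myokine median of -0.0785 was also inside the range of unmatched random lists (percentile 3.18). The lipid synthesis median fell to 0.0598 there and stayed outside the range (percentile 97.7). Scaling to equal totals raised the medians of the respiratory chain, endothelial and clock lists to 0.0780, 0.0840 and 0.0736. Those totals include the HIDATA rows and a single unnamed locus with 27.6% of all FPKM in WT, so this rise may follow from a few rows. Fewer genes enter at the minimum of 5; the cause was not tested further. Sequencing depth and the spread between animals are unknown, so no limit of detection can be given.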

Other observations

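The gene lists in this part were drawn up after seeing the data and count every tested gene, without the minimum mean FPKM of 1 set for the lists above. Of 36 tested proliferation genes 35 had a lower FPKM in mKO, 15 fell by the authors' q and none rose, or 23 fell when adjusted over the list alone, and the median log2 ratio was -0.21. Mki67, the gene of the proliferation antigen Ki-67, fell from 0.350 to 0.157 FPKM, Top2a from 0.792 to 0.381, Cdk1 from 0.385 to 0.157 and the mitotic kinase gene Aurkb from 0.372 to 0.0907. These levels are low: 10 of the genes had a mean FPKM of at least 1, of which 1 fell, with a median of -0.16, and 0 of the 36 genes passed when the statistic was read against a normal distribution.

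Epidermal genes were lower as well, with 6 of 14 tested genes past the authors' q, or 9 when adjusted over the list alone. All were in the lower direction, and the median log2 ratio was -0.77. This list was drawn up with the called genes in view, so these counts and the median were partly fixed by that choice. Of the 8 with a mean FPKM of at least 1, 3 fell and the median was -0.89, and 2 of the 14 passed the normal reading. Lor, a protein of the cornified envelope, fell from 0.589 to 0.103 FPKM and Krt10 from 2.86 to 1.26. Defb6 and Calm4 were listed at 0 in mKO and at 3.83 and 1.25 FPKM in WT, and Lgals7 was at 3.19 and 0.0341 FPKM without passing. Target genes of PPAR transcription factors, which overlap the fatty acid list, had 19 tested members, of which 6 fell and none rose by the authors' q, or 9 fell when adjusted over the list alone, and 16 were at lower FPKM in mKO, with a median of -0.17 and 0 past the normal reading; Plin2, a lipid droplet protein, fell 1.31-fold from 34.6 to 26.3 FPKM.

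Nnt, the mitochondrial transhydrogenase gene, rose from 54.4 FPKM (45.5 to 63.3) in WT to 71.1 (59.7 to 82.5) in mKO, and these intervals overlap. Whether this rise follows from the loss of Fundc1 was not tested. A row that joins Atcay and Nmrk2 went from 73.0 to 30.6 FPKM and passed the authors' q. The row that holds Mirg was listed at 2064 FPKM in WT and 0.729 in mKO and passed the authors' q. Its WT interval of 2061 to 2066 FPKM is also very narrow for its level, and whether Mirg itself changed was not tested. Among microRNA and snoRNA rows, 13 were listed at 0 in one group and at 100 FPKM or more in the other, and 0 of them passed the authors' q. An unnamed locus of 62 bp held 27.6% of all FPKM in WT, at 233810 FPKM beside 218787 in mKO.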
